A study of Mus musculus with 4 samples.

How the data were processed

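Total RNA from cultured mouse embryonic fibroblasts was profiled on 4 single-colour Affymetrix U74Av2 oligonucleotide arrays, 1 array for each combination of genotype (wild-type or Xiap knockout) and treatment (unstimulated, or 20 ng/ml TNF for 4 hours). Groups were taken from the sample titles. The deposited values are probe set intensities on a linear scale, called signals here. They were made with MAS5, per the submitters' processing notes. Its version, the background settings and any detection calls are not given in the sources used here. The deposited values hold 12488 probe sets per array. All 4 columns have a trimmed mean of 500.3 after 2% of the probe sets is left out at each end, so the arrays had been scaled to a common level before deposit.

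Probe sets were named through the platform's annotation table. A single gene symbol was listed for 10833 probe sets and several symbols for 396, while 1193 non-control probe sets had none. The 66 control probe sets were left out of percentiles and gene counts. Of 8251 genes, 8237 were matched by Entrez identifier to the RefSeq gene table, which was used to check symbols and to give chromosomes. No genome build is named for the arrays, so no coordinates are given. A gene was represented by its probe set with the highest mean signal over the 4 arrays. This mattered for 2073 genes with more than 1 probe set. Fold changes below are those of the probe set used, and other probe sets of the same gene can give smaller changes. No name was taken from a probe set with several symbols. Genes with near-identical relatives, such as the guanylate-binding proteins, the class I histocompatibility genes, the Ifi200 genes, Cyp4a12b and the Hspa1 pair, may share hybridisation and are uncertain.

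Signals were rescaled to the common trimmed mean, which changed nothing at the precision of the files (factor 1.0). They were then raised to a floor of 92.5, the 40th percentile of the pooled non-control signals, and converted to log2. A gene counted as measured in a comparison when at least 1 of the arrays compared was above the floor. This held for 6174 genes over all arrays, and 5130 genes were above the floor on all 4. A fold change with 1 array at the floor is a lower bound, written as at least N-fold. A floor of this kind understates the change of dim genes and removes the order among them.

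With 1 array per group, the comparisons of 2 arrays have no test and no replicate check. Genes at least 2-fold higher or lower (1 on the log2 scale) were counted. The difference of response is the log2 fold change with TNF in knockout cells minus that in wild-type cells. Each of 35 gene lists was summarised by its number of members past 2-fold and by its median log2 fold change. The percentile of that median among 10000 random lists of the same size, matched in 20 bins of mean signal, describes these arrays and is not a p-value. Some lists share genes.

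An additive model with genotype and TNF was fitted over the 4 arrays with limma (lmFit and eBayes with an intensity trend, 2-sided, Benjamini-Hochberg adjustment over 6174 genes, threshold 0.05). It has 1 residual degree of freedom per gene, which is the difference of response between the genotypes, and 5.62 prior degrees of freedom. Its p-values treat a true difference of response as error, rest mostly on the spread pooled over genes, and have no replicate cultures behind them. A genotype effect in this model cannot be told from any other difference between the wild-type and the knockout cultures. The 4 arrays were also split 2 against 2 by TNF, by genotype and across both, and genes past 2-fold were counted in each split. Each split contrasts means of 2 arrays, so the crossed split equals the difference of response divided by 2.

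The additive fit was tested on 20 simulated data sets of 6174 genes with normal noise taken from the crossed split and 200 changed genes per effect. For the TNF effect it recovered a median of 72.0% of genes changed by 1 on the log2 scale (range 55.0% to 90.0%) and 92.0% of those changed by 2 (80.0% to 98.0%). False calls made up a median of 1.22% of calls and at most 13.0%. For the genotype effect the recovered shares were 67.5% (53.0% to 90.0%) and 90.5% (85.0% to 95.0%), with false calls at a median of 1.16% and at most 17.7%. The simulation had no gene whose response differed between genotypes. Its noise was set by a robust SD per bin of signal, which gives genes with extreme differences little weight. False calls may therefore be more frequent in the arrays than in the simulation.

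The rule for named genes took, per comparison, the 10 genes with the highest and the 10 with the lowest log2 fold change, up to 4 members of each list past 2-fold by size of change (or the 2 largest where none passed), and Xiap. Gene lists, the design of the comparisons, thresholds and this rule were fixed before the data were examined. So were the alternatives: no rescaling, quantile normalization, equal medians, floors at the 20th and 60th percentile, no floor, thresholds of 1.5-fold, 3-fold and 3 robust SDs, the mean of all probe sets of a gene, eBayes with no trend, and an adjusted p threshold of 0.10. Counting bright genes only and the tests of explanations for single patterns were added after the data were seen. Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1.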

Results

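Mouse embryonic fibroblasts of wild-type and Xiap knockout genotype were compared by RNA expression profiling. Xiap encodes the X-linked inhibitor of apoptosis protein, a caspase inhibitor with ubiquitin ligase activity. Confluent cultures were either left unstimulated or exposed to 20 ng/ml tumour necrosis factor (TNF), a cytokine that activates the transcription factor NF-kB, for 4 hours. The design asks how fibroblasts respond to TNF and whether the response differs without Xiap. Each of the 4 combinations was measured on 1 array, so there are no replicates, every fold change below lacks a replicate check, and the number of arrays limits the precision. The arrays reported 12488 probe sets. Median signals were 183 for unstimulated wild-type, 151 for TNF-treated wild-type, 179 for unstimulated knockout and 173 for TNF-treated knockout cells. Genes above the signal floor numbered 5798, 5426, 5735 and 5660 in the same order. The ratio of the 3' to the 5' control probe sets, a measure of RNA integrity, was 0.757 to 0.815 for Gapdh and 1.08 to 1.17 for actin.

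Xiap itself was dim on all 4 arrays. Its brightest probe set had signals of 239 in unstimulated and 126 in TNF-treated wild-type cells, and of 180 and 120 in the corresponding knockout cells. The log2 ratio of knockout to wild-type was -0.41 without and -0.07 with TNF. The second probe set gave -0.30 without TNF and was below the floor on both TNF arrays, and the third was below the floor on every array. The part of the gene removed in the knockout is not given in the sources used here. Whether these probe sets lie inside it is therefore unknown, and they do not check the genotype labels. Among neighbours of Xiap on the X chromosome, Lamp2 and Stag2 were measured and neither differed 2-fold between genotypes in either state.

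In wild-type fibroblasts, TNF-treated cells carried much more transcript of inflammatory and interferon-inducible genes than unstimulated cells. Highest on floored values were Ch25h, a cholesterol hydroxylase gene, at 30.9-fold (signal 109 to 3355), and Gbp2, a guanylate-binding GTPase gene, at least 28.4-fold higher. The chemokine genes Cxcl1 (20.6-fold), Cxcl10 (at least 19.6-fold), Ccl7 (18.6-fold) and Ccl2 (12.8-fold) followed, with Ccl2 reaching a signal of 18414. H2-K2, a class I histocompatibility gene, was at least 18.6-fold higher, and the interferon-inducible Ifit1 and Ifi47 were 13.1-fold and at least 11.8-fold higher. The secreted pattern-recognition gene Ptx3 was 12.4-fold higher. Id2, an inhibitor of helix-loop-helix transcription factors, was 3.61-fold lower, and the imprinted zinc finger gene Peg3 was 3.75-fold lower.

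All 11 measured members of the NF-kB feedback list were at least 2-fold higher with TNF in wild-type cells (median log2 1.96, percentile 100 among random lists). They included Nfkbia (6.20-fold), which encodes the inhibitor that retains NF-kB in the cytoplasm, Bcl3 (at least 9.53-fold), the deubiquitinase gene Tnfaip3 (at least 6.07-fold) and Relb (5.50-fold). The other measured probe set of Relb gave a log2 change of 0.91, under 2-fold. Of 10 measured chemokines, 8 were at least 2-fold higher. Among adhesion, acute-phase and inflammatory enzyme genes 13 of 17 were higher, with the leukocyte adhesion gene Icam1 at least 9.03-fold, the prostaglandin synthase gene Ptgs2 at least 8.44-fold and the acute-phase gene Saa3 7.53-fold higher. The interferon response list had 17 of 26 members at least 2-fold higher (median log2 1.35, percentile 100), and the antigen presentation list 8 of 13, including H2-D1 (3.73-fold) and the immunoproteasome genes Psmb10 (3.57-fold) and Psmb8 (3.33-fold). Immediate early and AP-1 genes were higher in 14 of 28 cases, led by Cebpd (8.45-fold), at least 5.10-fold for Egr2, and 4.92-fold for Fosl1.

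Among cytokines and growth factors, 3 of 12 were at least 2-fold higher, with Il6 at least 4.66-fold and the macrophage growth factor gene Csf1 4.05-fold, and Lta was 3.18-fold lower. In the apoptosis list 3 of 24 were higher and 2 lower. The death receptor gene Fas was at least 8.09-fold, the BH3-domain gene Bid 3.87-fold and the inflammatory caspase gene Casp4 at least 3.01-fold higher, while Bnip3 was 2.14-fold lower. Of 5 measured inhibitor of apoptosis genes, Birc3 was at least 4.64-fold and Birc2 2.17-fold higher. Only 1 of 18 TNF receptor signalling genes, Tank, passed 2-fold (2.05-fold higher). No gene of the cell cycle (41 measured), heat shock (15) or endoplasmic reticulum stress (21) lists passed 2-fold. Over 5911 measured genes, 156 were at least 2-fold higher and 154 at least 2-fold lower, of which 28 and 43 are bounds. The lower calls came mostly from dim genes. The median log2 change was -0.28 in the dimmest of 5 equal groups of genes and 0.03 in the brightest, and quantile normalization left 192 genes higher and 82 lower.

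In Xiap knockout fibroblasts many of the same inflammatory genes were higher with TNF, and on floored values 3 chemokine genes stood highest. Ccl2 was 104-fold higher (signal 173 to 18083), Ccl7 72.6-fold and Ccl5 at least 50.4-fold. Gbp2 and Gbp3 were both at least 18.6-fold higher, the collagenase gene Mmp13 17.0-fold, Saa3 at least 15.7-fold, the chemokine gene Ccl9 13.3-fold and Icam1 at least 12.6-fold. Gbp2b was at least 9.93-fold higher and stayed below the floor on both wild-type arrays. The lowest genes on floored values were Ica1 (2.89-fold lower, although its other probe set was higher), Cyp4a12b (at least 2.65-fold), the lipid transfer gene Stard10 (2.55-fold) and Id2 (2.45-fold).

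By list, 9 of 11 NF-kB feedback genes were at least 2-fold higher in knockout cells (median log2 1.89, percentile 100), among them Nfkbie (6.22-fold) and Nfkbia (5.91-fold), and 8 of 10 chemokines. Adhesion and acute-phase genes passed in 9 of 17 cases, with the adhesion receptor gene Vcam1 4.48-fold higher. Antigen presentation genes passed in 9 of 14, with Psmb8 6.36-fold, Psmb10 5.12-fold and the invariant chain gene Cd74 4.56-fold higher. Interferon response genes were at least 2-fold higher in 6 of 24 cases (median log2 0.56, percentile 100), including the transcription factor gene Irf1 (9.10-fold). Immediate early genes were higher in 5 of 27 cases and lower in 1, Gadd45g. Fas (at least 7.02-fold) and Bid (4.63-fold) were the apoptosis genes past 2-fold of 25 measured, and Birc3 (at least 3.70-fold) the only one of 5 inhibitor of apoptosis genes. Csf1 (2.70-fold) was the only one of 10 cytokine genes. None of 18 TNF receptor signalling genes passed. Of 5868 measured genes, 87 were at least 2-fold higher and 24 lower, 22 and 4 of them as bounds. With a floor at the 20th percentile the lower genes numbered 166 and the higher genes 191.

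**Figure D1:**
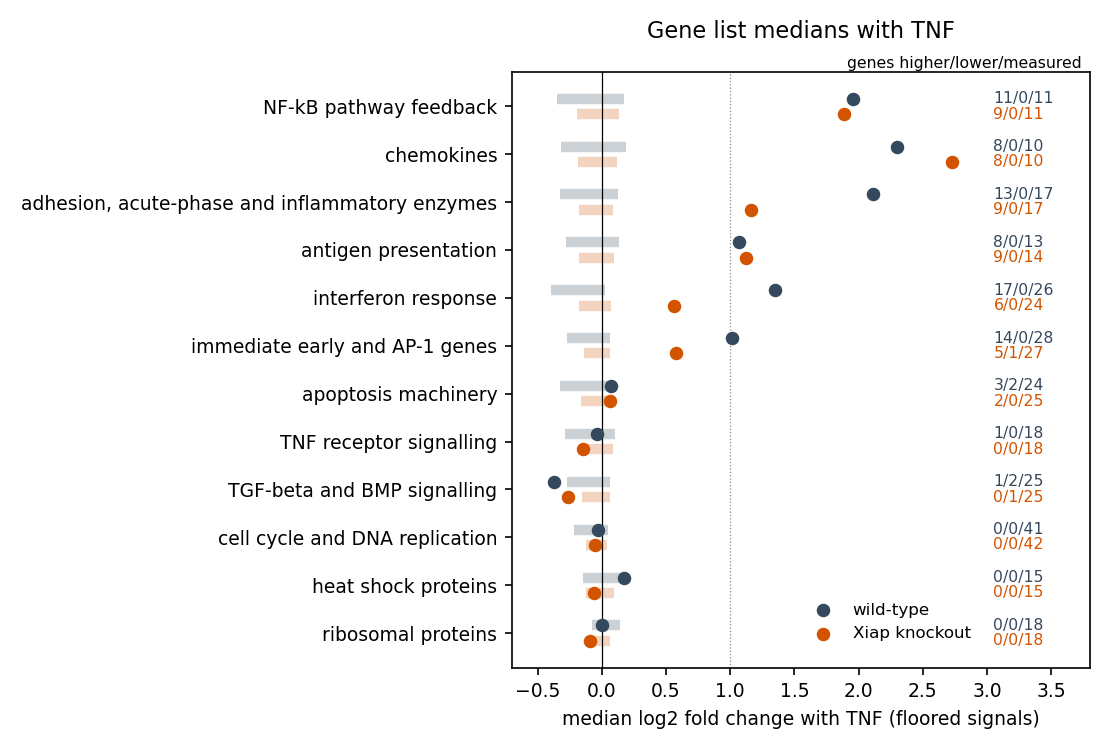
Median log2 fold change with TNF of 12 gene lists (points), in wild-type and Xiap knockout fibroblasts with 1 array per group; shaded bars span the central range of medians of 10000 random lists matched on signal, and the numbers give genes at least 2-fold higher, lower and measured. The NF-kB feedback medians lie at 1.96 and 1.89, and the interferon response medians at 1.35 in wild-type and 0.56 in knockout cells.

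The responses of the genotypes overlapped in part, with Gbp2, Ccl2 and Ccl7 among the 10 highest genes of both. Of 5605 genes measured in both, 142 were at least 2-fold higher in wild-type and 84 in knockout cells, and 66 were higher in both, where independent lists would share 2.13. Of 145 genes lower in wild-type and 22 in knockout cells, 6 were lower in both, against 0.57. No gene was past 2-fold in opposite directions. Across these genes the log2 responses correlated with a Pearson r of 0.586 and a Spearman rho of 0.401, although genes are not independent replicates. The Pearson r depended on the floor: it fell with a lower floor and further with none, as given below. In the additive limma fit, 79 genes rose with TNF and 10 fell at an adjusted p below 0.05 after Benjamini-Hochberg adjustment, and 864 of 6174 had an unadjusted p below 0.05. Nfkbia rose by 2.60 on the log2 scale (SE 0.10, adjusted p = 0.000264), Vcam1 by 2.53 (SE 0.17, adjusted p = 0.00152) and H2-D1 by 1.90 (SE 0.11, adjusted p = 0.00127), each higher in both pairs of arrays. Id2 fell by 1.57 (SE 0.23, adjusted p = 0.0286) and Id3 fell by 1.05 (SE 0.12, adjusted p = 0.0133), each lower in both pairs.

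By list, 10 of 11 NF-kB feedback genes rose in this limma fit over all genes, and 11 when adjusted over the list alone. The counts were 6 and 8 of 11 for chemokines (with 1 chemokine lower over the list alone), 8 and 12 of 18 for adhesion and acute-phase genes (1 lower), and 7 and 9 of 14 for antigen presentation (1 lower). Interferon response genes rose in 6 of 27 cases over all genes and in 16 when adjusted over the list alone. For immediate early genes these counts were 5 and 18 of 28 (1 lower). The TGF-beta and BMP signalling list held Id2 and Id3, which fell, and the BMP antagonist gene Grem1, which rose; adjusted over the list alone, 4 of its 26 genes rose and 9 fell. The size of the TNF count depended on the processing: with the mean of all probe sets of a gene 6 genes passed, with no intensity trend 18, and with quantile normalization 168. Of the 89 genes, 19 had an array below the floor, where effect and SE depend on the floor.

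**Figure D2:**
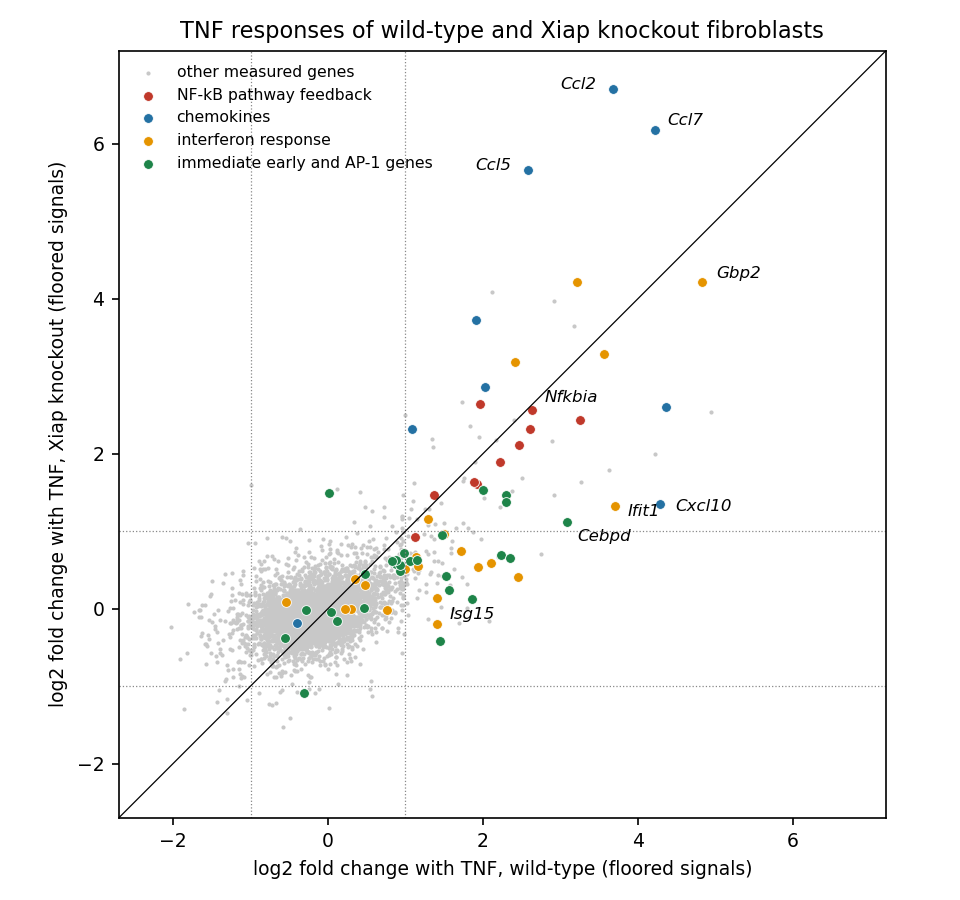
Log2 fold change with TNF in wild-type (horizontal axis) against Xiap knockout fibroblasts (vertical axis), 1 point per gene above the floor in both comparisons, on floored signals; dotted lines mark 2-fold and the solid line equal responses. NF-kB feedback genes lie near the line (Nfkbia 2.63 and 2.56), Ccl2 lies above it (3.68 and 6.70), and Isg15 lies below it (1.41 and -0.19).

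On floored values, single genes of several groups had responses of different size in the genotypes. Of 11 chemokine genes, 5 had a floored response at least 2-fold larger in the knockout and 2 a smaller one, of which the floor left 1 each open. The response of Ccl2 was 8.15-fold, of Ccl5 at least 8.46-fold, of Ccl7 3.89-fold and of Ccl9 3.53-fold that of wild-type cells, whereas that of Cxcl1 was smaller (log2 difference -1.76). For Ccl2 and Ccl7 the unstimulated knockout signal was lower (log2 ratio -3.05 and -2.10), and the signals with TNF were close, at 18083 against 18414 for Ccl2 and 6875 against 7577 for Ccl7. Mmp13 followed the same course, with a response 3.93-fold that of wild-type and an unstimulated log2 ratio of -1.60. Smaller in the knockout were the responses of Ptx3 (log2 difference -1.84), the transcription factor gene Cebpd (-1.96), the hyaluronan synthase gene Has2 (-2.24, a bound because its TNF-treated knockout signal lay below the floor), the ubiquitin-like modifier gene Isg15 (-1.61) and the adaptor gene Tradd (-1.30).

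Ptgs2, Cxcl10, Rsad2, Ch25h, Ifit1, Il6, Fos and Slfn2 had floored differences of -3.08 to -2.04, but in each an unstimulated knockout signal below the floor left the true difference open. For Ifit1 and Cxcl10 the sign turned with no floor, at 1.80 and 0.70. Of 27 interferon response genes, 7 had a floored response at least 2-fold smaller, 4 of them left open by the floor, and 1 a larger one (median floored log2 difference -0.48, percentile 0.0 among random lists). Immediate early genes showed 8 smaller, 2 of them left open, and 1 larger of 28 (median -0.46, percentile 0.0), and NF-kB feedback genes none past 2-fold of 11 (median -0.28, percentile 0.45). The random lists were matched on signal and not on TNF response. These percentiles therefore cannot tell a difference particular to a list from one shared by TNF-responsive genes. Over 6174 genes, 156 had a floored response at least 2-fold larger and 70 smaller in the knockout, of which 14 and 26 were left open, and no test of the difference was possible. With quantile normalization the counts were 102 and 102. Among 105 genes chosen by a mean response of at least 2-fold higher, the median log2 response was 1.92 in wild-type and 1.38 in knockout cells, the median difference was -0.34 (quartiles -0.92 and 0.20), and 70 lay within 2-fold. A floor at the 20th percentile turned the median of the chemokine differences from 0.82 to -0.02. At the main floor 11 of 20 chemokines on the array were measured. The lower floor can admit more of them, so these medians can cover different genes.

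Without TNF, the wild-type and knockout cultures differed widely, including in genes of the matrix and of developmental patterning. Penk, which encodes the opioid precursor proenkephalin, was 147-fold higher in knockout cells (17354 against 118), and Itm2a was at least 58.7-fold higher. The imprinted gene Mest (28.4-fold), the growth factor gene Clec11a (24.1-fold), Capn6 (20.3-fold) and Igfbp2 (18.7-fold) followed. The limb patterning genes Pitx1 (18.0-fold) and Shox2 (17.7-fold), the retinoic acid-binding gene Crabp2 (at least 17.8-fold) and the p53 target Perp (at least 16.7-fold) were also higher. In the other direction, the proteoglycan gene Dcn was 124-fold (15414 against 124) and Plac8 103-fold lower. C1qtnf3 was at least 35.5-fold, Col8a1 14.3-fold and Npy1r at least 15.7-fold lower, and the junction protein gene F11r had a log2 ratio of -4.64. The cyclin-dependent kinase inhibitor genes Cdkn2a and Cdkn2b were at least 23.3-fold and at least 17.0-fold lower.

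Cell cycle and replication genes were higher in unstimulated knockout cells as a group, with 10 of 42 at least 2-fold higher and none lower (median log2 0.58, percentile 100). Examples were the kinesin gene Kif11 (4.11-fold), Top2a (3.44-fold) and Rrm2 (2.51-fold), while the probe sets of Mki67 gave 1.71 and 0.01. Hox genes, which mark position along the body axis, went both ways with 6 higher and 8 lower of 24. Hoxa7 (at least 10.5-fold), Hoxc8 (10.2-fold), Hoxa5 (at least 6.53-fold) and Hoxb6 (4.99-fold) were lower. Mesenchymal transcription factors had 6 higher and 3 lower of 23, with Twist2 6.75-fold and Foxd1 4.34-fold lower. Matrix genes had 5 higher and 9 lower of 45, Lum being at least 8.11-fold lower and Fmod 7.04-fold higher. Imprinted genes had 4 higher and 5 lower of 17, among them Grb10 (16.6-fold higher) and Meg3 (7.25-fold lower). Xist, transcribed from the inactive X chromosome, was at least 13.3-fold higher in knockout cells (1232 against 34.3), and the Y-linked Eif2s3y was at least 5.29-fold lower (2.8 against 489).

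Other lists also differed between the unstimulated cultures. Of 15 measured genes of the p53 list 5 were higher, including Ccng1 (3.06-fold) and Cdkn1a (2.71-fold), and 1, Cdkn2a, was lower. That list is not limited to genes that p53 induces, so Cdkn2a is not counted here as a p53 target. Of 18 myofibroblast genes 5 were higher, such as the calponin gene Cnn1 (4.03-fold), and 2 lower, such as Ccn2 (2.75-fold). TGF-beta and BMP genes had 4 of 26 lower, namely Id2 (4.96-fold), Fst (4.68-fold), Grem1 (4.03-fold) and Id4 (at least 2.85-fold). Oxidative stress genes had 1 of 24 higher, Sod3 (4.40-fold), and 2 lower, Gpx3 (7.94-fold) and Gstm2 (7.07-fold). The other measured probe set of Gstm2 gave a log2 ratio of only -0.31. Glycolysis and hypoxia genes had 4 of 22 higher, including Bnip3 (3.09-fold) and Ldha (2.26-fold). Chemokines had 2 of 8 higher and 4 lower. Over 6062 measured genes, 276 were at least 2-fold higher and 285 lower in the knockout, 54 and 70 of them as bounds. Every such difference compares a single culture of each genotype.

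**Figure D3:**
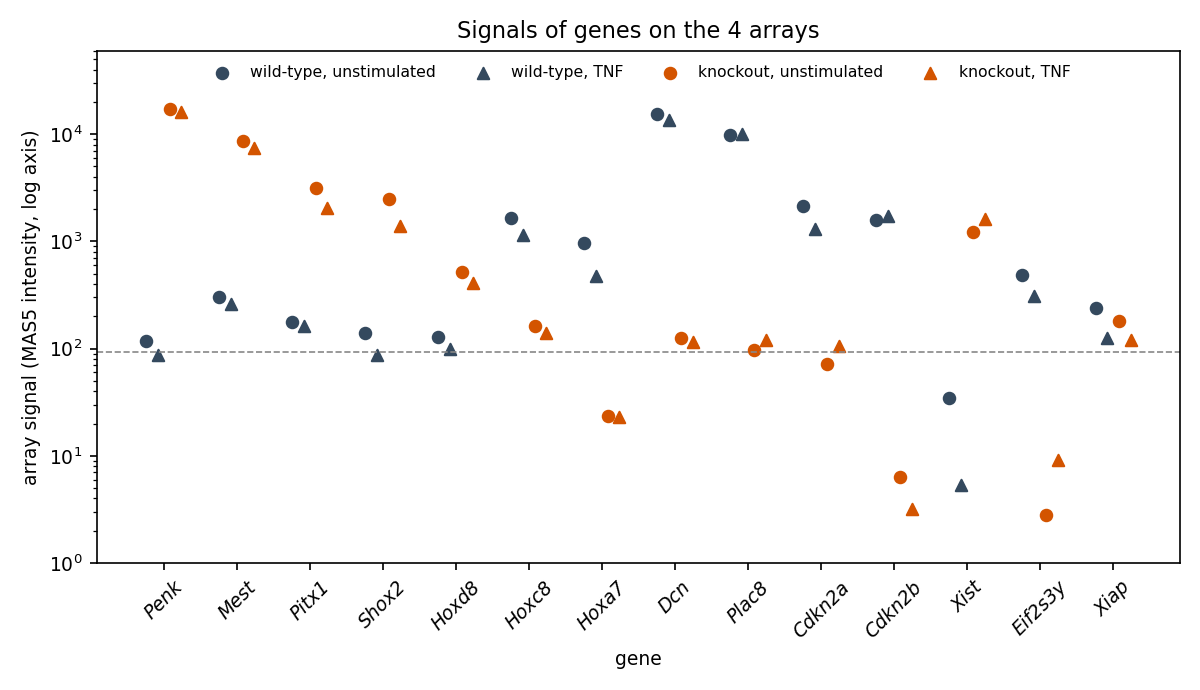
Signals of 14 genes on the 4 arrays (log axis, MAS5 intensity), with circles for unstimulated and triangles for TNF-treated cells and 1 array per point; the dashed line is the floor of 92.5. Penk lies at 118 and 86.4 in wild-type and at 17354 and 16162 in knockout cells, and Dcn at 15414 and 13693 against 124 and 115, while the Xiap signals lie between 120 and 239.

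Under TNF, the knockout cells had lower levels of interferon-inducible and early response transcripts than wild-type cells. Part of this was present without TNF for interferon response genes (median log2 ratio -0.38, percentile 0.19). Adhesion and acute-phase genes were also lower then (median -0.45, percentile 0.14). The immediate early median without TNF, -0.18 (percentile 5.92), lay inside the central range of random lists, with 3 of 27 genes at least 2-fold higher and 1 lower. Without TNF, Ifi204 was 4.00-fold, Ifit3 at least 2.89-fold and Mmp3 at least 7.98-fold lower in the knockout. Past 2-fold, 2 of 22 interferon response genes were lower and 3 higher, including Irgm1 (3.65-fold) and Isg20 (2.07-fold). With TNF, of 26 interferon response genes, 10 were at least 2-fold lower and 1, Ifi202b, higher (median log2 -0.69, percentile 0.0). Ifit3 was 11.9-fold, Ifit1 9.60-fold, the antiviral gene Rsad2 at least 5.90-fold and Ifi204 5.42-fold lower, although the other probe set of Ifi204 gave -0.06. Immediate early genes were lower in 10 of 28 cases and higher in 1 (median -0.79, percentile 0.0), with Fos at least 5.94-fold, Cebpd 5.28-fold, Nr4a1 4.15-fold and Egr1 4.07-fold lower. Adhesion and acute-phase genes were lower in 8 of 18 cases, including Ptgs2 (at least 8.44-fold), Slfn2 (5.77-fold) and Mmp3 (4.83-fold). None of 11 NF-kB feedback genes and 1 of 13 antigen presentation genes, Psmb9 (at least 2.24-fold higher), passed 2-fold.

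Chemokines differed both ways with TNF. Cxcl10 was 7.70-fold and Cxcl12 3.81-fold lower in knockout cells, and Ccl5 was 5.59-fold and Cxcl5 4.84-fold higher. Of 13 cytokine genes 2 were higher and 3 lower, with Il6 at least 4.66-fold and the lymphatic growth factor gene Vegfc at least 4.94-fold lower. Penk was at least 175-fold, Igfbp2 31.4-fold and Sfrp2, a secreted Wnt modulator gene, 16.3-fold higher, and Dcn was 119-fold, Plac8 84.6-fold and Frzb at least 16.5-fold lower. The log2 ratio of F11r was -3.20 with TNF, closer to 0 than without it. Cell cycle genes were higher in 11 of 42 cases and lower in none (median log2 0.75, percentile 100). Over 5852 measured genes, 329 were at least 2-fold higher and 293 lower, 80 and 62 of them as bounds. Dim genes read lower on the TNF-treated wild-type array, as described above, and enter this comparison too.

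Many genes differed between the genotypes in the same direction with and without TNF. Of 5740 genes measured in both states, 276 were at least 2-fold higher in knockout cells without TNF and 327 with it. Of these, 178 were higher in both states (15.7 for independent lists). The lower genes numbered 279 and 280, with 176 lower in both (13.6), and Chrne alone went in opposite directions. The log2 differences correlated across genes with r = 0.812 and rho = 0.671. In the additive limma fit, 706 genes were higher and 645 lower in the knockout at a Benjamini-Hochberg adjusted p below 0.05, with 887 in total when no intensity trend was used. The floored values of Penk, below the floor on the TNF-treated wild-type array, differed by 7.32 (SE 0.12, adjusted p = 7.34e-07). Mest differed by 4.83 (SE 0.11, adjusted p = 2.4e-06), Dcn by -6.93 (SE 0.11, adjusted p = 7.34e-07) and Plac8 by -6.54 (SE 0.13, adjusted p = 1.9e-06), each in the same direction in both pairs of arrays. Of the 1351 genes called for genotype in the fit with the trend, 187 had an array below the floor, where effect and SE depend on the floor. Splitting the 4 arrays by genotype gave 508 genes past 2-fold, splitting by TNF 130, and the crossed split 15. The crossed split is the difference of response divided by 2. Its count is therefore below the 226 genes with a difference of response past 2-fold.

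By list in the limma fit, 25 of 42 cell cycle genes were higher in the knockout over all genes, and 28 when adjusted over the list alone, where 1 was lower. Among 25 Hox genes 6 were higher and 6 lower (7 and 10 adjusted over the list alone). Among 23 mesenchymal transcription factors 8 were higher and 4 lower (9 and 5 adjusted over the list alone). Matrix genes split into 10 higher and 14 lower of 45 (11 and 16 adjusted over the list alone), and imprinted genes into 6 and 7 of 17 (7 and 7 adjusted over the list alone). Of 6 sex-linked genes 3 were higher and 1 lower, over all genes and adjusted over the list alone. How many fibroblast lines of each genotype were used is not given in the sources used here. With 1 array per genotype and TNF state, genotype and line cannot be separated in any case.

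Among the remaining lists, no cholesterol synthesis gene of 18 passed 2-fold with TNF in either genotype, and in unstimulated knockout cells 1 of 18, Mvd, was lower (2.45-fold). Among endoplasmic reticulum stress genes 3 of 21, including Ero1a (3.25-fold), were lower in unstimulated knockout cells. Of heat shock genes (15) and ribosomal protein genes (18), none passed in any comparison. Of 14 housekeeping genes 1, Polr2a, passed, being 2.86-fold higher in knockout than wild-type cells with TNF. The probe set used for Polr2a changed with TNF by a log2 of -0.88 in wild-type and 0.51 in knockout cells. Its other measured probe set changed by only -0.05 and 0.17. Copper and metallothionein genes passed in 1 of 8 cases with TNF in the knockout, Mt2 (2.39-fold higher), and Cp was at least 2.44-fold lower in knockout than wild-type cells with TNF. Markers of other cell types were mostly near the floor. Macrophage (8 measured), epithelial (3), skeletal muscle (13) and neural (7) markers had no member past 2-fold between the unstimulated cultures. In the same comparison 1 of 6 endothelial markers, Eng (3.33-fold), 2 of 6 adipocyte markers, including Lpl (at least 10.6-fold), and 1 of 6 cartilage and bone markers, Mgp (4.17-fold), were lower in the knockout. With TNF, the endothelial receptor gene Flt1 was 7.57-fold higher in wild-type and at least 2.76-fold higher in knockout cells. Between the TNF-treated cultures all 3 measured endothelial markers passed 2-fold (median log2 -2.20, percentile 0.06). With no floor all 12 endothelial markers on the array counted as measured, and the median over them was 0.11. That median covers other genes as well. Eng and Flt1 were above the floor on both TNF-treated arrays. On floored values Eng was 4.91-fold and Flt1 4.59-fold lower and Cd34 2.43-fold higher in the knockout. In that comparison 1 of 6 macrophage and 1 of 6 neural markers were higher, and 1 of 5 adipocyte and 1 of 6 cartilage and bone markers were lower.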

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

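The comparison of starting levels, the crossed split and the test of Hox and mesenchymal genes were chosen after the results they explain were seen; the setting of bright genes only was also added then, with the bound for its ratio written before that ratio was seen. The groups hold 1 array each, so comparing an array with others of its group was not possible.

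Chrne, a muscle acetylcholine receptor gene, was lower in knockout cells without TNF (log2 -1.27) and higher with TNF (log2 1.32), and the difference was not tested. The control probe set for Fas, left out of the gene counts, was higher with TNF by at least 3.67 in wild-type and by 2.82 in knockout cells on the log2 scale. Of 1589 probe sets without a single gene symbol, 10 were at least 2-fold higher with TNF in both genotypes and 0 were lower in both.

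More genes were at least 2-fold lower with TNF in wild-type (154) than in knockout cells (24). If dim probe sets on the wild-type TNF array were the cause, quantile normalization should have removed most of the 154. It left 82, between the bounds set for and against this cause, so an array effect on dim genes and a cellular one cannot be told apart. Among 2608 bright genes, 23 were lower in wild-type and 4 in knockout cells, a ratio of 5.75, in line with a difference that is not limited to dim genes. A difference between the arrays in labelling or hybridisation stays open, because each condition has 1 array.

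Fewer interferon response genes were at least 2-fold higher with TNF in knockout (6) than in wild-type cells (17). A higher start in the knockout is argued against for most of these genes: those past 2-fold in wild-type only had a median unstimulated log2 ratio of -0.511 (quartiles -0.694 and 0.246), below 0 in 6 of the 9 measured, but Irgm1 (1.87) and Ifi35 (1.00) did start higher, and for them it stays open. Scaling and floor do not account for all of it. The knockout count stayed at or below 0.474 of the wild-type count under each scaling and floor alternative. With a floor at the 20th percentile the knockout count was 9 and the wild-type count 19, so a part played by the floor stays open. A weaker response of all TNF-responsive genes cannot be told apart from one specific to interferon genes: the median difference was -0.793 for 12 responsive interferon genes and -0.322 for 93 others, a gap of -0.471 at percentile 9.67 of random draws. Genotype, other differences between the lines and chance between single arrays stay open, as untested.

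In both states, 354 genes differed at least 2-fold between the genotypes in the same direction. Noise between arrays as the whole cause is argued against by the crossed split, which gave 15 genes where the genotype split gave 508, with 130 as the highest of the other splits. There are 3 splits, too few for a share under 0.05. With a lower floor or none, the crossed count was a larger share of the genotype count, as given below. A part played by noise therefore stays open where signals were dim. Xist and Eif2s3y indicate embryos of different sex, and sex chromosomes held 3.107% of these genes against 2.809% of measured genes. Most of the 354 genes therefore lie on other chromosomes. This share cannot decide on sex as a cause, because too few sex chromosome genes were measured to make up most of the 354. Effects of sex on genes of other chromosomes were not tested, so sex stays open. Different body positions or mesenchymal lineages of the cultures stay open: 18 of 44 Hox and mesenchymal transcription factor genes differed the same way in both states (random lists, median 3 and 95th percentile 6), but this count restates the differences that prompted the explanation and does not test it. The loss of Xiap itself stays open and was not tested, because the number of lines per genotype is not given in the sources used here.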

How the results depend on the processing

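No paired analysis was possible by replicate because each group has 1 array; the additive limma fit already uses the pairs of arrays within each genotype and TNF state. Leaving an array out would have emptied its group. Depth, here signal over background, limits genes near the floor, and the counts past 2-fold moved with it. Counting bright genes only was chosen after the data were seen. Where no construction is named, the cause was not tested. A lower floor admits dim genes by construction, and a stricter threshold passes fewer genes. Of 3110 values of named genes under scaling, floor and probe set alternatives, 2704 changed by less than the limit set for a move, 400 moved and 6 reversed. Of 1225 list medians, 1196 kept their place, 25 moved and 4 reversed. Signals as deposited moved none of these.

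The counts past 2-fold were given for the TNF response in wild-type fibroblasts, the TNF response in Xiap knockout fibroblasts, the contrasts of knockout against wild-type, unstimulated and of knockout against wild-type, TNF, and the difference of TNF response, knockout minus wild-type. They were 310, 111, 561, 622 and 226. In that order they were 893, 357, 981, 1134 and 844 with a floor at the 20th percentile, 135, 62, 316, 330 and 70 at the 60th, and 1402, 685, 1284, 1613 and 1407 with no floor. At 1.5-fold they were 1152, 400, 1474, 1618 and 979, and at 3-fold 92, 43, 203, 228 and 50. With bright genes only they were 54, 23, 144, 151 and 24. At 3 robust SDs the last 4 were 246, 244, 246 and 143, and the first stayed within 1.5 times. The split of higher and lower wild-type genes, 156 and 154, became 192 and 82 with quantile normalization and 185 and 122 with equal medians; that of the difference, 156 and 70, became 102 and 102 with quantile normalization.

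The limma count for TNF, 89, became 168 with quantile normalization, 48 with equal medians, 6 with the mean of all probe sets, 18 with no trend and 166 at an adjusted p below 0.10. The limma count for genotype, 1351, became 893 with the mean of all probe sets and 887 with no trend. Genes counted for the size of 3 splits: genotype, TNF and crossed, were 508, 130 and 15. They were 840, 354 and 129 with a floor at the 20th percentile, 294, 66 and 7 at the 60th, 1179, 706 and 411 with no floor, 1339, 474 and 138 at 1.5-fold, and 194, 52 and 1 at 3-fold. The correlation of TNF responses, 0.586, fell to 0.446 with a floor at the 20th percentile and to 0.298 with no floor, and that of genotype differences, 0.812, to 0.603 with no floor.

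Reversed values were the gene list median: chemokines; difference of TNF response, knockout minus wild-type (-0.0208 with a floor at the 20th percentile), the sex-linked median under TNF (-0.48 with a floor at the 20th percentile and with no floor) and the endothelial median under TNF (0.11 with no floor). A lower floor or none lets dim members count as measured, so these list medians can cover more genes than the main ones. For the difference of response of single genes, Csf1r became -0.0603 and Peg3 -0.0065 with a floor at the 60th percentile, Flt1 0.16 with a floor at the 20th percentile and with no floor, and Cxcl10 0.70 and Ifit1 1.80 with no floor. No scaling alternative shifted the median of all genes by over 0.1.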

Other observations

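Genes of chromosome 10 were higher in the knockout cultures as a block. The median log2 ratio of knockout to wild-type, averaged over both states, was 0.61 (1.52-fold) for its 262 measured genes (quartiles 0.24 and 0.91), and 84.4% of them were higher in the knockout. The medians were 0.56 without and 0.62 with TNF. The highest median among 2000 random gene sets of that size was 0.136, although 9 of 20 chromosomes had a median outside the range of their random sets, so passing that range was common. Smaller shifts were seen on chromosomes 7 and 13 (0.24 on each, 74.7% and 75.9% of genes higher), and the lowest median was that of chromosome 15 (-0.18). The chromosome was noticed after all chromosomes were compared.

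A hypothesis is that the knockout line may carry an extra copy of chromosome 10, as cultured fibroblasts can gain chromosomes. A gain of the whole chromosome predicts a shift along its full length. Split into 4 equal parts by gene order, it had medians of 0.67, 0.61, 0.62 and 0.56, and the lowest part, at 0.557, lay above the bound of 0.3 set before the parts were computed. Bright genes of the chromosome had a median of 0.57. A shift along the full length was not particular to chromosome 10. The 4 parts had medians of 0.22 to 0.29 on chromosome 7 and of 0.16 to 0.33 on chromosome 13. A ratio of knockout to wild-type also does not show which of the cultures changed. No DNA was measured, so a copy gain in all cells, a larger gain in part of them and other chromosome-wide causes cannot be separated.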
